A study of Rattus norvegicus with 8 samples.

How the data were processed

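Genomic DNA from 8 rat renal carcinomas was measured by 2-colour array comparative genomic hybridization, in which tumour DNA and a reference DNA compete for the same probes and the ratio of their signals follows relative copy number. Each array carried tumour DNA labelled with Cy5 and ear-skin DNA from a rat of the same sex and cross labelled with Cy3. The labels do not state whether ear and tumour came from the same animal, and no array had the dyes exchanged. Of the 8 tumours, 2 came from non-irradiated rats, 3 from rats irradiated on gestational day 19 (GD19) and 3 from rats irradiated on postnatal day 5 (PND5). Groups, sex and dose were taken from the labels. The 2 non-irradiated tumours and GD19 tumours 1 and 2 shared slide 1, and GD19 tumour 3 and the 3 PND5 tumours shared slide 2.

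Per the file headers, the scanner output came from Agilent Feature Extraction 10.5.1.1 with protocol CGH_105_Dec08 and build rn4, whereas the submitters' processing notes name version 10.7.3.1. Per the file headers, the processed signal of each channel is an intensity after background subtraction, spatial and multiplicative detrending and a linear dye normalization, and the unprocessed median spot and background signals are also intensity values. The log ratio in the deposited scanner output is the log10 of tumour over ear processed signal. It matched the log10 of the ratio of processed signals within 0.0001 in at least 99.95% of spots on every array. Quality flags, per the file headers, are 0 or 1 for non-uniform spots, outlying replicates, saturation and signal well above background. The deposited table of the whole series holds log2 ratios, judged from the values, since its scale and centring are not given in the sources used here; its correlation with the log2 ratios of the scanner output, across probes, was 0.963 to 1.00.

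For the copy number profiles the log2 ratio of tumour over ear processed signal was computed for 174012 feature spots per array. Spots with an outlier flag in either channel were left out, which removed 130 to 170 spots per array. Replicate spots were averaged to 170012 probes, and each array was centred on the median of its autosomal probes. Between 99.79% and 99.85% of tumour signals and 99.80% to 99.84% of ear signals were well above background and 0 spots were saturated. The number of arrays limits the precision of every comparison between groups. Arrays were compared for duplicates by their correlation across probes, and no pair exceeded 0.866. No hybridization was repeated to show the correlation of a duplicate, so this does not exclude duplicates.

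Each chromosome was divided into segments by recursive circular binary segmentation. Neighbouring segments were kept apart when their means differed at a Z of 6 or more against a noise SD taken from adjacent probes. A segment was called a gain or loss at a mean at least 0.25 from 0 over at least 5 probes. The Z that ranks calls compares the mean of a call with 0 and had no lower limit. Adjacent calls of one direction were merged. A loss counted as interstitial when both of its ends lay at least 10 probes from the ends of the chromosome, and a chromosome counted as wholly changed when 80% of its probes lay in calls of one direction. The rule that no segment under 5 probes was split off was set after a first run had divided the profiles too finely. Segmentation was tested on simulated data, with segments placed in shuffled profiles of the 8 arrays. At a mean of -0.45, 78.8% of segments of 10 probes and 100% of segments of 50 probes were recovered with 80% reciprocal overlap, and at -0.3 the shares were 32.5% and 96.2%. Shuffled profiles without added segments gave 238 calls over the 8 arrays, of at most 20 probes each.

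Means of 1-Mb bins with at least 10 autosomal probes, 2559 bins in all, were compared with limma 3.58.1 in a model with 1 mean per group and moderated variances. The contrasts were irradiated (the equal-weight mean of GD19 and PND5) minus non-irradiated, PND5 minus GD19, and each irradiated group minus non-irradiated. A model with an intercept alone tested departure of all 8 tumours from 0. Bins passed at a Benjamini-Hochberg adjusted p under 0.05. On simulated data, a shift of 0.2 was recovered in 89.6% of changed bins for irradiated minus non-irradiated, 85.1% for PND5 minus GD19, 85.1% for GD19 minus non-irradiated, 83.6% for PND5 minus non-irradiated and 94.0% for departure from 0, among 2559 bins. At a shift of 0.1 the shares in the same order were 74.6%, 61.2%, 44.8%, 52.2% and 95.5%. A count of 0 bins therefore does not exclude shifts of that size. Each simulated shift was equal in all tumours of the shifted group, with independent noise per bin and tumour. The shares therefore say nothing on changes carried by only some tumours of a group. Single values per tumour were compared by two-sided exact permutation tests over 28 splits of 6 against 2 tumours (smallest possible p 0.0357) or 20 splits of 3 against 3 (smallest possible p 0.1), and counts of tumours by Fisher's exact test. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and R 4.3.3, with figures drawn in matplotlib 3.10.9.

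Apart from what is named below, the groups, contrasts, thresholds, alternatives and gene lists were fixed before the data were examined. By the rule for named items, the text names Tsc2 in every tumour, list genes within calls (at most 30), the 10 bins with the largest differences per contrast among those that passed, at most 10 regions called in 3 or more tumours by number of tumours and then length, and up to 3 calls under 10 Mb per tumour by Z. Calls of at least 1 Mb outside this rule, and the low-level shifts of GD19 tumour 1, were named after their values were seen. The 7 lists covered the TSC-mTOR pathway, neighbours of Tsc2, renal carcinoma genes, cell cycle genes with tumour suppressors and oncogenes, DNA damage response, antigen receptor loci and kidney segment genes. The scanner output pairs probes with positions and not with gene names, and an rn4 annotation was not used here. The test of single genes, the probes of Tsc2 and a correction for GC content were therefore not run, and GRCr8 was used only to say on which chromosome a list gene lies. The results for some list genes are not reported here. In place of Tsc2, the probes at 13 to 15 Mb of chromosome 10 were summarized, a window set after the fixed design and after the files were opened, but before any log ratio by position had been examined. No value of the window therefore counts as planned, and the alternatives planned for the Tsc2 probes were applied to it.

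Alternatives covered normexp background correction (offset 50, on median signals), no centring, centring on the mode, the deposited table of the series, spots with outlier flags kept, dim probes left out, Z of 5 or 8, call thresholds of 0.15 or 0.4, at least 3 or 10 probes per call, at least 30 probes per bin, X included, sex or slide as a covariate, the median in the chromosome 10 window, and leaving out each tumour in turn. Chosen after seeing the data were removal of the probe pattern shared by the arrays (for each array, the probe-wise median of the others times a fitted slope), interstitial losses of at least 1 Mb or of more than 20 probes alone, and fits within each slide.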

Results

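Copy number was profiled in renal carcinomas of F1 hybrids of F344 and Eker rats. Eker rats carry a germline mutation of Tsc2, a tumour suppressor whose product restrains mTOR complex 1, and develop renal tumours. The design asked whether whole-body gamma irradiation (137Cs, 2 Gy at 0.7 Gy/min), given on gestational day 19 or postnatal day 5, left a mark on the copy number of the tumours. There were 2 tumours from non-irradiated rats (both male), 3 from GD19 rats (all female) and 3 from PND5 rats (2 female and 1 male). Each tumour was hybridized once against ear-skin DNA. The labels number the tumours without saying whether any came from the same animal, so p-values measure the spread between these tumours alone.

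The arrays had median processed signals of 1006 to 1054 for tumour DNA and 1002 to 1039 for ear DNA. The noise SD between adjacent probes was 0.197 and 0.164 (log2) in non-irradiated tumours 1 and 2, 0.181, 0.184 and 0.144 in GD19 tumours 1 to 3, and 0.156, 0.158 and 0.145 in PND5 tumours 1 to 3. A probe pattern ran through the log2 ratios of 7 arrays, whose pairwise correlations across probes were 0.708 to 0.866. Non-irradiated tumour 1 correlated with these at 0.219 to 0.355. Probes are not independent replicates, and mean correlations of the 7 arrays were 0.791 within a slide and 0.783 between slides.

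Tumours were first compared with ear DNA one by one. The longest called change was a loss of nearly the same part of chromosome 10 in 2 tumours, 1 from each irradiated group. In GD19 tumour 3 it ran from 11730607 to 62056458 (rn4), a length of 50.3 Mb, with a mean log2 ratio of -0.46 (SE 0.00297 over 3807 probes). In PND5 tumour 3 it ran from 10965409 to 62779373, a length of 51.8 Mb, with a mean of -0.56 (SE 0.00318 over 3935 probes). The losses covered 45.1% and 46.6% of the probes of chromosome 10. Over the interval lost in both, the other tumours had means of 0.03 (non-irradiated 1), -0.05 (non-irradiated 2), -0.03 (GD19 1), -0.02 (GD19 2), -0.02 (PND5 1) and -0.01 (PND5 2).

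Both losses were interstitial, since the chromosome returned to the level of the ear DNA on either side. Proximal to both losses GD19 tumour 3 and PND5 tumour 3 had means of 0.00 and 0.01, and distal to both 0.01 and -0.01. The breakpoints of the 2 tumours were 0.765 Mb apart proximally and 0.723 Mb apart distally. In the 54 probes from 10965409 to 11725651, PND5 tumour 3 had a mean of -0.55 and GD19 tumour 3 a mean of 0.01 (SE 0.0217). In the 74 probes from 62083186 to 62779373 the means were -0.52 and 0.01 (SE 0.0192). Under 12 settings of the processing, the distal breakpoint did not move in either tumour. The proximal one of PND5 tumour 3 lay between 10958207 and 10965409. In GD19 tumour 3 the long loss started at 11730607, except with the shared probe pattern removed, where it started at 12192313. In that setting a separate loss of 33 probes ran from 11730607 to 12073825 (mean -0.44), so the lost part still began at 11730607.

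**Figure D1:**
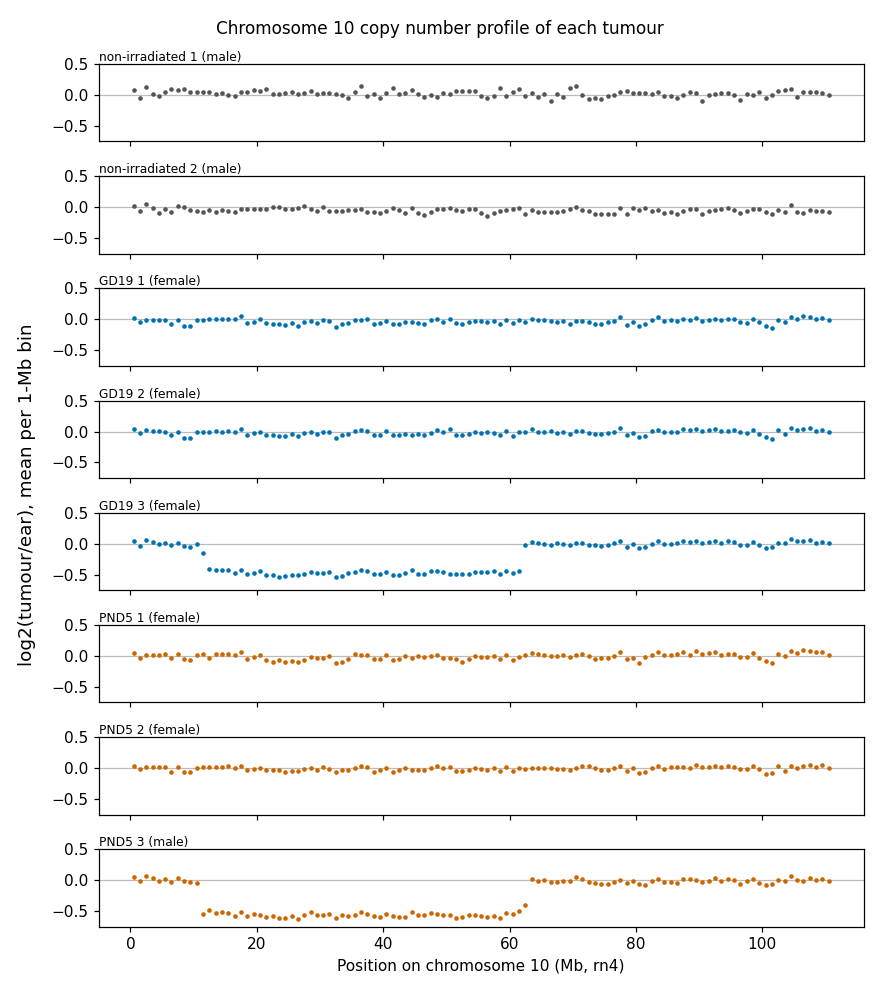
Mean log2 ratio of tumour over ear DNA per 1-Mb bin (vertical axis) along chromosome 10 in Mb of rn4 (horizontal axis), with 1 panel per tumour and 1 point per bin. GD19 tumour 3 and PND5 tumour 3 lie near -0.46 and -0.56 over about 50 Mb, while the other 6 tumours stay near 0.

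Chromosome 10 carries Tsc2 in GRCr8, between Pkd1, which codes for polycystin-1, and Nthl1, a DNA glycosylase. The window at 13 to 15 Mb that stood in for Tsc2 (211 probes) was lost in GD19 tumour 3, with a mean of -0.43, and in PND5 tumour 3, with a mean of -0.52. It was not lost in non-irradiated tumours 1 and 2 (0.02 and -0.06), GD19 tumours 1 and 2 (0.01 and 0.00) or PND5 tumours 1 and 2 (0.03 and 0.02). Of the gene lists, chromosome 10 of GRCr8 holds 5 of 20 TSC-mTOR genes (Tsc2, Mlst8, Rptor, Rps6kb1 and Nprl3), all 17 matched neighbours of Tsc2, 1 of 19 renal carcinoma genes (Flcn) and 2 of 23 DNA damage genes (Brca1 and Rad50). Of 20 names in the antigen receptor list 3 were matched (Iglc1, Rag1 and Rag2), 0 of them on chromosome 10. With most names unmatched, this does not show where the antigen receptor loci lie. Whether a given gene lies inside the losses in rn4 was not analysed here.

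GD19 tumour 3 carried a further large change, a gain of the first part of chromosome 14. From 1041443 to 49820759 its mean log2 ratio was 0.25 (SE 0.00352 over 3089 probes). It was called as 2 gains, from 1041443 to 20574633 and from 30953048 to 49820759, each with a mean of 0.26. The rest of the chromosome had a mean of -0.01, and the same interval lay between -0.04 and 0.03 in the other 7 tumours. List genes on chromosome 14 in GRCr8 are Egfr, Nf2, Ikzf1 and Depdc5.

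**Figure D2:**
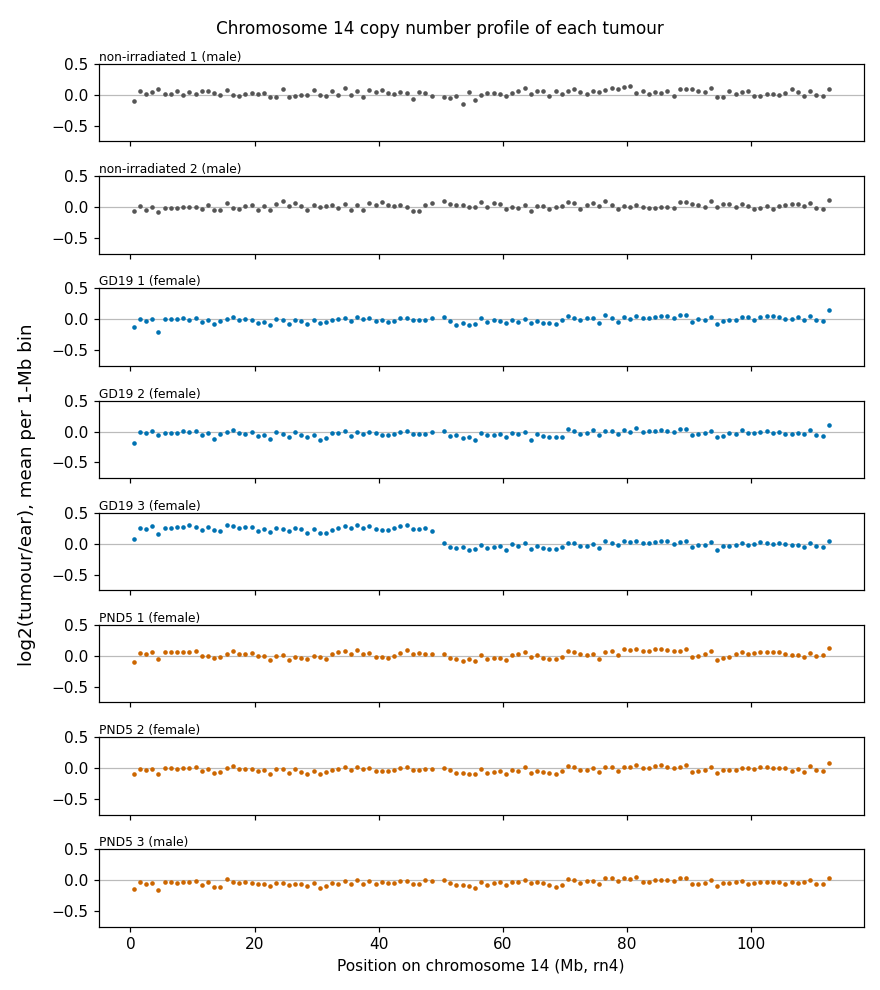
Mean log2 ratio of tumour over ear DNA per 1-Mb bin (vertical axis) along chromosome 14 in Mb of rn4 (horizontal axis), with 1 panel per tumour and 1 point per bin. GD19 tumour 3 lies near 0.25 up to 49820759 and near 0 beyond it, and the other 7 tumours stay near 0 throughout.

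Smaller changes were also found in single tumours. Non-irradiated tumour 2 had a called loss of 2.97 Mb on chromosome 15, from 28755027 to 31725412, with a mean of -0.63 (SE 0.0418 over 66 probes). The other tumours lay between -0.09 and -0.01 there. For this and the other changes named here, a difference in the ear DNA in place of the tumour DNA was not tested. GD19 tumour 3 had a gain of 703 kb on chromosome 8 (24225589 to 24928930, mean 0.31, 42 probes) and a loss of 252 kb on chromosome 2 (110222940 to 110475306, mean -0.43, 16 probes). Non-irradiated tumour 1 had a gain of 248 kb on chromosome 6 (28370403 to 28618176, mean 0.28, 29 probes). It also had a gain of 5 probes on that chromosome (127942237 to 127973845, mean 0.69), where the other tumours lay between -0.39 and -0.18. The shuffled profile of this array gave 5 calls of at most 13 probes, 0 of them losses. A call of 5 probes therefore does not by itself establish a change. Whether the low values of the other tumours there belong to the shared probe pattern was not tested. A call of 10 probes on the X chromosome of GD19 tumour 2 (128975457 to 130318899) had a mean of 0.39 with an SD over probes of 0.56.

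GD19 tumour 1 had low-level shifts of whole chromosomes that stayed under the call threshold of 0.25, and these were picked out after their values were seen. Chromosome 4 had a mean of 0.17 over 12352 probes, against -0.03 to 0.03 in the other 7 tumours. Chromosome 5 had a mean of -0.15, against -0.07 to -0.03 in the others. With the call threshold lowered to 0.15, chromosome 4 of GD19 tumour 1 counted as wholly gained, whereas at 0.25 no chromosome of any tumour counted as wholly changed. List genes on chromosome 4 in GRCr8 include Met, Braf, Mitf, Vhl and Rheb, and 3 of the 20 kidney segment genes (Aqp1, Atp6v1b1 and Gpnmb). The 7 list genes on chromosome 5 include Mtor, Arid1a and Sdhb, and 2 of the 27 cell cycle genes, tumour suppressors and oncogenes (Cdkn2a and Cdkn2b).

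**Figure D3:**
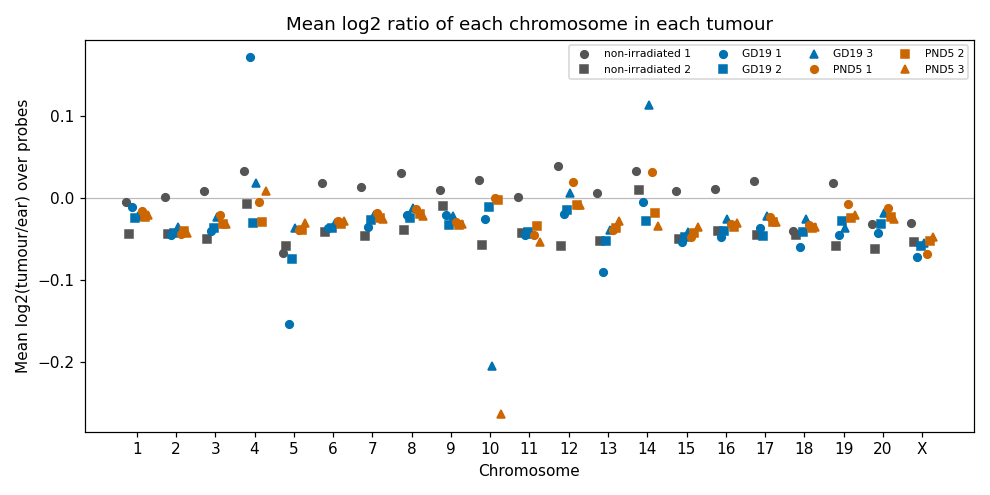
Mean log2 ratio of tumour over ear DNA over all probes of a chromosome (vertical axis) for chromosomes 1 to 20 and X (horizontal axis), with 1 point per tumour. Chromosomes 4 and 5 of GD19 tumour 1 (0.17 and -0.15), chromosome 10 of GD19 tumour 3 and PND5 tumour 3, and chromosome 14 of GD19 tumour 3 lie apart from the other tumours.

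Regions called in 3 or more tumours were losses, most of them short. There were 40 such regions, 0 of them gains, and 37 were under 200 kb, with a median of 5 probes and 46.6 kb. The region called in all 8 tumours lay on chromosome 5 from 134053022 to 134631216 (40 probes, mean -0.41), and 32 of its probes gave signals near background on some array. Regions on chromosome 13 (11665017 to 11717955, 6 probes) and chromosome 14 (20586493 to 20633942, 5 probes) were called in every tumour except non-irradiated tumour 1. A region of 5 probes on chromosome 10 (32377900 to 32413877) was called in 5 tumours and lay inside the long losses of GD19 tumour 3 and PND5 tumour 3, which were counted here on chromosome 10. The 6 next in number of tumours, each of 5 probes and called in 6 tumours, lay on chromosomes 3, 5, 8, 9, 13 and 19. Among regions called in fewer, a loss on chromosome 14 of GD19 tumour 2 (847884 to 946799, mean -0.59), with 6 of 10 probes near background on some array, overlapped losses in 3 other tumours. Losses of 5 probes in PND5 tumour 3 on chromosome 6 (mean -0.70) and chromosome 2 (mean -0.67), with 1 and 3 such probes, each overlapped losses in 2 others. A longer region on chromosome 15, from 31829692 to 32228525 (27 probes), was called in 5 tumours and lay between -0.36 and -0.13 in all 8. Calls of 20 probes or fewer also arose from shuffled profiles, 238 over the 8 arrays. Each array was shuffled on its own, so these calls do not bear on losses that recur at the same probes. Of the 40 regions, 33 lay below 0 in all 8 tumours. Only 3 were called in non-irradiated tumour 1, whose profile correlated least with the other arrays.

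Across all tumours, 1374 of 2559 bins departed from 0 in limma at an adjusted p under 0.05, 105 higher and 1269 lower. Tumour DNA was labelled with Cy5 on every array, and 7 arrays shared a probe pattern. This test therefore does not separate copy number from a dye or probe bias common to the arrays. The shifts were small, with a median size of 0.05, and 79 bins exceeded 0.1. The largest was at 134 to 135 Mb of chromosome 5 (-0.28, SE 0.0261, adjusted p 8.15e-05, lower in 8 of 8 tumours). It was followed by 32 to 33 Mb of chromosome 10 (-0.20, lower in 7 of 8, with the 2 tumours that lost this part at -0.54 and -0.60) and 31 to 32 Mb of chromosome 15 (-0.19, SE 0.0198, adjusted p 0.000113, lower in 8 of 8). The other bins of the 10 with the largest departure lay on chromosome 10 (33 to 34 and 46 to 47 Mb), chromosome 5 (113 to 114, 27 to 28, 100 to 101 and 67 to 68 Mb) and chromosome 3 (84 to 85 Mb), with means of -0.18 to -0.14. The balance of directions depended on the centring, with 413 higher and 699 lower without centring and 10 higher and 1905 lower with centring on the mode. With the probe pattern shared by the arrays removed, 0 bins departed from 0 in limma (0 at an unadjusted p under 0.05), a result that the subtraction itself brings about.

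Irradiated and non-irradiated tumours were compared to ask whether irradiation in early life was followed by more copy number change. The 2 tumours with the chromosome 10 loss were both irradiated, but the loss was absent from the other 4 irradiated tumours. A loss spanning the window at 13 to 15 Mb was found in 2 of 6 irradiated tumours (95% Clopper-Pearson interval 4.33% to 77.7%). Shorter losses inside the window, 1 of them called in non-irradiated tumour 2, were not counted. A loss spanning the window was found in 0 of 2 non-irradiated tumours (upper limit 84.2%), with a two-sided Fisher exact p of 1. With 2 losses among the 8 tumours no table lies further toward irradiation, so this test could not tell irradiation from chance. The mean log2 ratio of the window was -0.15 ± 0.25 (SD, n = 6) in irradiated and -0.02 ± 0.06 (SD, n = 2) in non-irradiated tumours, a difference of -0.13 that was smaller than the spread among irradiated tumours (two-sided exact permutation p = 0.714). It was -0.08 without GD19 tumour 3 and -0.06 without PND5 tumour 3.

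The share of autosomal probes in called gains and losses was 1.22% ± 1.73 (SD, n = 6) in irradiated and 0.254% ± 0.216 (SD, n = 2) in non-irradiated tumours (two-sided exact permutation p = 0.643). GD19 tumour 3 (4.02%) and PND5 tumour 3 (2.75%) accounted for the higher mean. The other irradiated tumours lay at 0.111% to 0.155%, between the 0.101% of non-irradiated tumour 1 and the 0.407% of non-irradiated tumour 2. With the shared probe pattern removed, those other irradiated tumours lay at 0.0475% to 0.109%. Non-irradiated tumours 1 and 2 then lay higher, at 0.329% and 0.128%. In non-irradiated tumour 1 this share came from 70 gains and 1 loss, all under 1 Mb, against 9 gains and 3 losses before. That array had the lowest slope on the shared pattern (0.38), and whether the subtraction brought in these gains was not tested. The mean difference of 0.965 percentage points was 0.405 without GD19 tumour 3, and 3.16 with a call threshold of 0.15 (two-sided exact permutation p = 0.607). Interstitial losses numbered 39.2 ± 23.4 (SD, n = 6) in irradiated and 43.5 ± 57.3 (SD, n = 2) in non-irradiated tumours (two-sided exact permutation p = 1). The 2 non-irradiated tumours had 3 and 84, so the sign of this difference rested on which of them was counted, with a difference of 36.2 without tumour 2 and -44.8 without tumour 1. Most of these losses were short, and shuffled profiles gave 0 and 58 losses for non-irradiated tumours 1 and 2 and 17 to 63 for irradiated tumours. Interstitial losses of at least 1 Mb numbered 1 each in non-irradiated tumour 2, GD19 tumour 3 and PND5 tumour 3 and 0 in the rest. Whole-chromosome changes numbered 0 in each of the 8 tumours.

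At the level of 1-Mb bins, 0 of 2559 differed between irradiated and non-irradiated tumours in limma (673 at an unadjusted p under 0.05, smallest adjusted p 0.0883). Leaving out non-irradiated tumour 2 gave 711 bins, 687 of them lower in irradiated tumours, and non-irradiated tumour 1, whose profile correlated at 0.219 to 0.355 with the others, then stood alone for its group and was assumed to vary like them. Leaving out non-irradiated tumour 1 gave 3 bins, all at 28 to 31 Mb of chromosome 15, where non-irradiated tumour 2 carried its loss. With slide as a block 12 bins passed, all on chromosome 14 within the gain of GD19 tumour 3 and all lower in irradiated tumours. The PND5 part of that contrast is estimated through GD19 tumour 3, the only tumour of another group on slide 2. Non-irradiated tumours were all male and all on slide 1. Within slide 1, GD19 tumours 1 and 2 against the 2 non-irradiated tumours gave 0 bins in limma (187 at an unadjusted p under 0.05). With sex as a covariate there were 0 bins in limma (123 at an unadjusted p under 0.05). GD19 tumours were all female, so the sex term was estimated within the PND5 tumours alone. It rests on PND5 tumour 3, the only irradiated male, which carries the chromosome 10 loss. This fit therefore cannot separate sex from irradiation. Among means of the 21 chromosomes, the smallest exact permutation p (two-sided) was 0.0357, for chromosome 9 (difference -0.03), and 0.643 after Benjamini-Hochberg adjustment over the 21.

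PND5 and GD19 tumours were compared to ask whether the age at irradiation mattered. Each group held 1 tumour with the chromosome 10 loss and 2 without it. The window at 13 to 15 Mb had a mean of -0.16 ± 0.31 (SD, n = 3) in PND5 and -0.14 ± 0.25 (SD, n = 3) in GD19 tumours (two-sided exact permutation p = 1). The share of altered autosomal probes was 0.998% ± 1.52 (SD, n = 3) in PND5 and 1.44% ± 2.24 (SD, n = 3) in GD19 tumours (two-sided exact permutation p = 0.5). The difference was -0.443 percentage points at the call threshold of 0.25, -5.02 at 0.15, which takes in the low-level shifts of GD19 tumour 1, and 0.0351 at 0.4. Interstitial losses numbered 45.7 ± 35.1 (SD, n = 3) in PND5 and 32.7 ± 3.51 (SD, n = 3) in GD19 tumours (two-sided exact permutation p = 1), with PND5 tumour 3 at 86 and the other 5 irradiated tumours at 22 to 36. The 3 against 3 design allowed no p below 0.1. Signs of these differences turned under some alternatives. With the shared probe pattern removed, the difference in interstitial losses was -7.67. Without PND5 tumour 3 it was -7.17 and that in the window 0.16, and without GD19 tumour 3 the difference in altered probes was 0.847. The difference in the window was also above 0 without GD19 tumour 1 (0.05) or GD19 tumour 2 (0.05).

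In limma 0 of 2559 bins differed between PND5 and GD19 tumours (18 at an unadjusted p under 0.05). With slide as a block 47 bins passed, all lower in PND5 tumours, of which 46 lay on chromosome 14 between 1000001 and 49000000 and 1 at 24 to 25 Mb of chromosome 8. Both places are gains of GD19 tumour 3, the only GD19 tumour on the slide of the PND5 tumours. Within slide 2, the 3 PND5 tumours against GD19 tumour 3 gave 27 bins in limma (59 at an unadjusted p under 0.05), but the spread there comes from the PND5 tumours alone, so this describes GD19 tumour 3 and not its group.

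Each irradiated group was also set against the non-irradiated tumours. GD19 tumours gave 0 bins in limma (591 at an unadjusted p under 0.05, smallest adjusted p 0.142), and PND5 tumours gave 0 bins in limma (536 at an unadjusted p under 0.05, smallest adjusted p 0.144). Without non-irradiated tumour 2 the counts were 658 and 566. Without non-irradiated tumour 1 they were 3 and 3, each at 28 to 31 Mb of chromosome 15. With slide as a block, PND5 against non-irradiated tumours gave 30 bins, 29 of them on chromosome 14 and 1 on chromosome 8. That contrast has no slide in common, so the block estimate passes through the GD19 tumours.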

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

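The screens of percent gained, chromosome means, array correlations and slopes on the shared probe pattern were chosen after the data had been examined, whereas interstitial losses were a planned measure. A value was picked out when its gap to the nearest other sample was large against the range of its group (Dixon's criterion). This held in 6 of 28 groups of values. Chance alone picks out about 1 in 20 groups if values are normal and groups independent. These groups are not independent, since non-irradiated tumour 1 was picked out by both its correlation and its slope. The share of 6 in 28 therefore cannot be set against that rate.

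GD19 tumour 3 stood apart from the other 5 irradiated tumours with 1.55% of autosomal probes in called gains, most of them on chromosome 14. PND5 tumour 3 stood apart with 86 interstitial losses, of which 2 spanned more than 20 probes, and its shuffled profile gave 63 losses. With the shared probe pattern removed it had 20, fewer than GD19 tumours 1 and 2 (23 each), and no longer stood apart. GD19 tumour 1 had the highest mean log2 ratio of chromosome 4 among irradiated tumours (0.17) and the lowest of chromosome 5 (-0.15). With the shared probe pattern removed, its mean for chromosome 4 was 0.17, while that of chromosome 5 from 82590 to 133839039 went from -0.16 to -0.11 and was no longer called at a threshold of 0.15. Non-irradiated tumour 1 had a mean correlation of 0.280 with the other arrays and a slope of 0.380 on the shared probe pattern, against slopes of 0.836 to 1.13 in the other 7.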

How the results depend on the processing

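Removal of the shared probe pattern, the size limits on losses and the fits within slides were chosen after seeing the data. The chromosome 10 window was set after the files were opened but before log ratios by position were examined, so none of its values counts as planned. The other alternatives were planned. Of 260 recomputed values, 235 kept their direction or stayed within the limits set for them, 15 turned sign and 10 counts moved from or to 0. Differences in whole-chromosome changes were 0 in the main run and could not turn sign, so they count among the 235 whatever their value. Bin counts of 0 that stayed 0 are also among the 235. A loss spanning the chromosome 10 window was called in 2 tumours under all 13 alternatives run. The difference between irradiated and non-irradiated tumours kept its sign for altered probes (0.405 to 3.16) and for the window (-0.174 to -0.0559), with no exact p below 0.429.

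Values that turned sign were as follows, and their cause was not tested. For altered probes, PND5 minus GD19 was 0.0637 with mode centring, 0.0351 at a threshold of 0.4, and -1.32 to 0.847 with 1 tumour left out (highest without GD19 tumour 3). For interstitial losses, irradiated minus non-irradiated was 1.33 in the series table, 10.3 at Z of 5, 2.5 at Z of 8, 9.83 with at least 3 probes, 5.17 with the shared pattern removed, and -44.8 to 36.2 with 1 tumour left out (without non-irradiated tumours 1 and 2). PND5 minus GD19 was -7.67 with the pattern removed, -1 for losses over 20 probes, and -7.17 to 24.8 with 1 tumour left out (lowest without PND5 tumour 3). The window difference for PND5 minus GD19 ran from -0.163 to 0.162 with 1 tumour left out.

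Bin counts moved from 0 with slide as a block to 12 (irradiated minus non-irradiated), 47 (PND5 minus GD19) and 30 (PND5 minus non-irradiated). With 1 tumour left out they ran from 0 to 711 for irradiated, 0 to 658 for GD19 and 0 to 566 for PND5 minus non-irradiated. The extremes and 3 bins in each contrast came from leaving out non-irradiated tumours 2 and 1. Bins departing from 0 ran from 1173 to 1592 with 1 tumour left out, and were 0 with the shared pattern removed, by construction. Of 10 splits of the 6 irradiated tumours, all 10 gave as many bins as the real split (0, highest other 0), which a real count of 0 brings about, so this comparison says nothing.

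No paired analysis was possible because the labels pair no tumours across groups. An rn4 genome and annotation were not used here, so the GC correction, the test of single genes and the Tsc2 probes were not run. Signal near background limited 472 probes.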

Other observations

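All tests in this part were chosen after the result was seen, except that of the ear channel in the chromosome 10 loss. GD19 tumour 1 carried further low-level shifts beyond chromosomes 4 and 5. The last part of chromosome 13 (83720554 to 111131228) had a mean of -0.18 against -0.05 in the rest of that chromosome, and the last part of chromosome 1 (208637349 to 267909731) a mean of 0.10 against -0.04. The first 4991075 bases of chromosome 17 had a mean of -0.14. In the other 7 tumours these intervals of chromosomes 13 and 1 lay between -0.06 and 0.02 and between -0.05 and -0.02. The shares of cells that follow also assume unchanged ear DNA, which was tested for chromosome 10 alone. If each change were the loss or gain of 1 copy in otherwise diploid cells, the ratios would correspond to 55.0% of cells for chromosome 10 in GD19 tumour 3, 64.1% in PND5 tumour 3, 37.8% for chromosome 14 in GD19 tumour 3, 71.0% for chromosome 15 in non-irradiated tumour 2 and 25.1% for chromosome 4 in GD19 tumour 1.

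The chromosome 10 loss in GD19 tumour 3 and PND5 tumour 3 may be a somatic deletion, arisen separately in the 2 animals. The share of tumour cells in the samples was not measured here, so whether part or all of the tumour cells carried it stays open. The other 6 tumours had means of -0.05 to 0.03 there, which argues against a probe bias shared by the arrays as the whole cause. With the shared probe pattern removed, the weaker of the 2 means was -0.432. Those other means largely fix that value, so it adds no separate support. GD19 tumour 3 had a mean of 0.0085 where PND5 tumour 3 alone was lost, which argues against DNA of PND5 tumour 3 mixed into it. PND5 tumour 3 had -0.04 in the chromosome 14 gain of GD19 tumour 3. The ear signal differed from the mean of the 6 other arrays by at most 0.0266, so the shift lies in the tumour channel (-0.437 and -0.505). Irradiation and chance cannot be told apart as the source, because with 2 losses among 8 tumours the Fisher exact p is 1 (two-sided) even when both are irradiated. Whether the losses took the normal allele of Tsc2 was not tested, because these ratios do not separate alleles.

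The low ratios at 134 Mb of chromosome 5 in all 8 tumours may come from sequence that is missing from both tumour and ear DNA. In that interval 32 of 40 probes gave signals near background, and the median ear signal was at most 2.00% of that of all probes, which argues against loss from a normal copy number. All 4 runs of at least 5 consecutive dim probes in the genome lay there. Over the 8 brighter probes the means were -0.24 to -0.07. A difference between these hybrids and the strain of the reference genome stays open and was not tested.

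The low ratios at 31829692 to 32228525 of chromosome 15 in all 8 tumours were not those of dim probes, as 0 of 27 probes lay near background. With the shared probe pattern removed, the means ran from -0.12 (PND5 tumour 2) to 0.11 (PND5 tumour 3), though the subtraction would also take out a change present in all tumours. Non-irradiated tumour 1, which carries little of that pattern, then lay at -0.10, or -1.14 SD of the 7 other arrays, but a low ratio of full size would lie at only -1.93 SD, so this test could not exclude probe bias, which stays open. This test and its limits replaced a first one after its result was seen, in which the gap was -2.96 standard errors over probes and argued against probe bias, by a measure that leaves out the spread between arrays. The interval starts 104 kb beyond the end of the loss in non-irradiated tumour 2, and no biological explanation was tested.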
